A study of Homo sapiens with 6 samples.

How the data were processed

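The series measured RNA in MDA-MB-231 cells, an established line from a human triple-negative breast cancer, infected with lentivirus carrying a control short hairpin RNA or 1 of 2 hairpins against PD-L1, the immune checkpoint ligand encoded by CD274. The groups follow the sample titles: control, hairpin 1 and hairpin 2, with 2 libraries each. Libraries were prepared from total RNA with a strand-preserving kit and read from both ends, per the labels. The labels do not say whether the libraries of a group came from separate cultures or infections, so every p-value measures only the spread between these libraries.

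The submitters' notes name, without role or order, the hg19 genome build, Picard, TopHat2 2.0.14, featureCounts 1.4.6-p2 and DESeq2. The strand setting of the read counting and the gene annotation are not given in the sources used here. The deposited signal is a column of normalised reads per library, kept separate for each replicate, for 6502 genes that the authors list as downregulated. The design text gives as criteria counts over 100, folds over 1.5 and p under 0.02. Genes outside this list were not analysed here, so no count of changed genes over the genome can be made and every count below describes the list. A deposited table of enriched gene ontology terms gives, per the file headers, numbers of genes, a fold enrichment (a score of observed over expected genes) and a p-value for each term, and it does not state whether that p-value was adjusted. A deposited list of DNA damage genes gives 410 symbols and no measurement.

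The spacing of the deposited values was examined column by column. Control values had 15 significant digits, and 401 constants from 1 to 5 were tried as multipliers that restore the same number of digits in the knockdown columns. The hairpin 1 values regained them after multiplication by 2.2 for 98.7% of genes in each library, and by 1.9 in replicate 1 and 1.93 in replicate 2 for most of the other 90 genes. The hairpin 2 values regained them after multiplication by 2.6 for 99.98% of genes in each library. For the control columns the constant was 1. For nearly all genes, the deposited knockdown value thus equals a value on the control columns' number grid divided by such a constant, called a divisor here. The reason for the divisors is not given in the sources used here. After multiplication, values in each column lay within 0.01 of whole multiples of 1 step for 99.98% of genes or more. That step, taken as the value of 1 read, gave 50494961 and 38306498 reads in the listed genes of the control libraries, 46747160 and 43226714 with hairpin 1, and 61968223 and 52214709 with hairpin 2. These sums cover the listed genes only and are not library depths, which are unknown. The smallest rebuilt read number of any listed gene ran from 291 to 649 between libraries. Because no listed gene has few reads, the rebuilt numbers were used as read counts only in alternatives and not in the main test.

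The main test was limma 3.58.1 in R 4.3.3 on the base 2 logarithm of the deposited value plus a pseudocount of 1. It fitted 3 group means over all 6 libraries, with 3 residual degrees of freedom and 3.88 prior degrees of freedom from the spread shared over genes. The contrasts were the mean of both hairpins minus control, each hairpin minus control, and hairpin 1 minus hairpin 2. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 6502 genes, with a threshold of 0.05. Tests, gene lists, named genes and most alternatives were chosen before the data were examined. The plan held edgeR for whole counts and limma for normalised values, and edgeR was not used because the table holds normalised values of a selected list. Every comparison was repeated with the divisors removed, meaning each knockdown value multiplied back by its constant. That second scale was chosen after seeing the data, and results are given on both.

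Each of 28 gene lists had been fixed with the plan. They cover homologous recombination, end joining, mismatch repair, base excision repair, nucleotide excision repair, Fanconi anemia genes, damage checkpoint, DNA replication, the RNA exosome, interferon response, antigen presentation, immune checkpoint ligands, NF-kB cytokines, p53 targets, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, mitosis, mesenchymal program, epithelial genes, large chromatin genes, KRAB zinc finger genes, replication histones, mitochondrial transcripts, fibroblast genes and blood cell genes. The 23 lists with at least 5 listed members were tested with camera from limma at a preset correlation of 0.01, and again with the correlation estimated from the data, adjusted over those lists. Camera compares the members with the other listed genes by moderated t-statistics, in which each change is divided by its SE. As deposited, where every listed gene fell, these statistics depend on the spread of each gene as well as on the size of its fall. A camera call as deposited thus does not by itself show a larger or smaller fall. With estimated correlation camera uses only the 3 residual degrees of freedom of the fit. A call lost there can thus reflect the few libraries as well as correlation among genes. Of 8 further lists, chosen after seeing the data, 7 were tested in the same way.

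Named genes followed a rule fixed with the plan: CD274, the 20 largest falls in the mean of both hairpins with a mean above 100 and every knockdown library below both control libraries, up to 4 members of each list by largest fall, the 10 largest falls of the deposited DNA damage list, the 5 largest hairpin differences in each direction, and NBN, BRCA1, RAD50, ATM, EXOSC10 and DIS3 whatever their values. The rule named 129 genes. For enriched terms it took the 10 smallest deposited p-values.

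Gene position, transcript length and GC content came from GENCODE release 29 on GRCh38, which is not the build named by the authors. Of the listed genes, 6476 had a length and GC content, 6236 by symbol and 240 by synonym. The overlap of the hairpins was compared with 100 simulations of unchanged groups that share the control libraries. The limma fit was tried on 6502 simulated genes with the spread of the values with the divisors removed and no shift of all genes. Each simulated library was centred on its median difference from control, which the main test does not do. That fit recovered 99% of genes with a log2 change of 1 and 73% with a log2 change of 0.25, with 8 calls among unchanged genes. These figures are thus not error rates of the main test on the deposited scale. Scaling and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

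Alternatives were pseudocounts of 0.1 and 5, median-of-ratios and total scaling of the rebuilt reads over the listed genes, precision weights, a replicate block, each library left out in turn, only the compared groups in the fit, an adjusted p threshold of 0.01, the 4 knockdown libraries as 1 group, and for the overlap a control library of its own for each hairpin. The planned edgeR and DESeq2 tests and edgeR's trimmed mean scaling were not used, since the deposited values are not whole counts and cover a selected list. A filter on low values removed no gene and was not run as a separate setting.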

Results

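Total RNA was sequenced from MDA-MB-231 cells to ask how RNA levels change when PD-L1 is depleted. PD-L1 is a membrane ligand that restrains T cells, and it is made by many tumour cells themselves. The groups were a control hairpin, hairpin 1 and hairpin 2, with 2 libraries each. Values were normalised reads for the 6502 genes that the authors list as downregulated, so genes that rose or stayed level on the authors' scale were not analysed here. The reads rebuilt for these genes ran from 38306498 to 61968223 per library, and the full depth of the libraries is unknown. The smallest rebuilt number for any gene in any library was 291 reads, so few reads did not limit the values. Across genes, the replicates of a group had a Pearson correlation of log2 values of 0.9990 for control, 0.9988 for hairpin 1 and 0.9990 for hairpin 2, and genes are not independent replicates. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries.

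The knockdown columns carry the divisors described with the processing, 2.2 for nearly all genes with hairpin 1 and 2.6 for hairpin 2. On the deposited scale the median log2 change of the listed genes against control was -1.19 with hairpin 1, -1.35 with hairpin 2 and -1.26 for the mean of both. Removing the divisors brought these medians to -0.055, 0.030 and -0.0043. The list also had bounds. The largest deposited ratio to control was 0.680 with hairpin 1 and 0.679 with hairpin 2, the smallest deposited knockdown value was 200.1, and the deposited means of the hairpins never differed by more than 2.00 times. The design text states neither the floor on knockdown values nor the limit on the hairpin ratio.

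**Figure D1:**
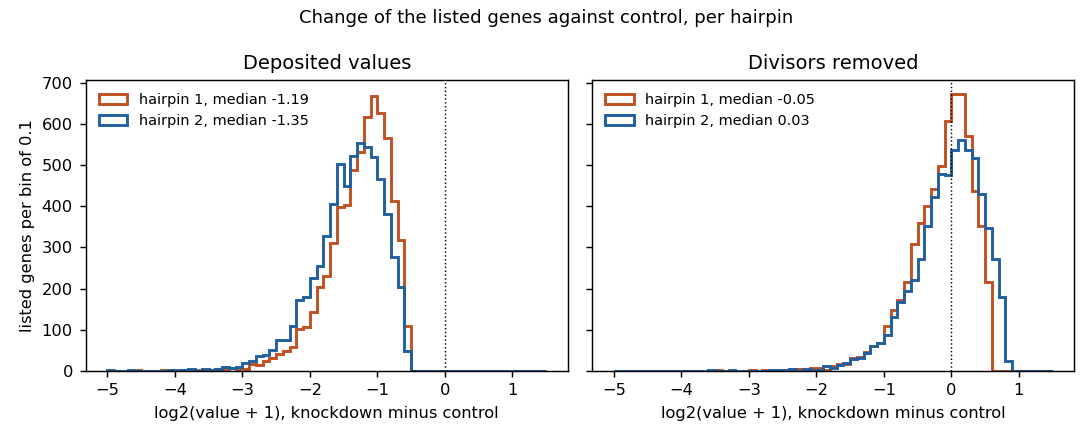
Number of listed genes (y axis) by log2 change against control (x axis) for hairpin 1 and hairpin 2, on the deposited scale and with the divisors removed. The medians move from -1.19 and -1.35 to -0.055 and 0.030.

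CD274, the gene targeted by both hairpins, was lower in all 4 knockdown libraries than in both control libraries, on the deposited scale and with the divisors removed. It lies on chromosome 9 from 5450503 to 5470566 on the forward strand of GRCh38, with annotated transcripts of 6 and 7 exons. The deposited values were 4525 and 4533 in control, 1371 and 1351 with hairpin 1, and 1494 and 1580 with hairpin 2. Their means were 4529 ± 5.06 (SD, n = 2), 1361 ± 14.6 (SD, n = 2) and 1537 ± 60.5 (SD, n = 2), so that 30.1% of the control level remained with hairpin 1 and 33.9% with hairpin 2. With the divisors removed the hairpin means were 2994 ± 32.1 (SD, n = 2) and 3996 ± 157 (SD, n = 2), which left 66.1% and 88.2% of the control level. The limma log2 change for both hairpins was -1.65 (SE 0.030, adjusted p 1.4e-09) on the deposited scale and -0.39 (SE 0.030, adjusted p 1.6e-05) with the divisors removed. On that last scale, log2 changes of all listed genes had an SD of 0.47 with hairpin 1 and 0.51 with hairpin 2. There, 1001 listed genes with hairpin 1 and 906 with hairpin 2 were lower by over 1.5 times. CD274 was lower with hairpin 1 than with hairpin 2, by a log2 difference of -0.17 (limma adjusted p 0.0025) as deposited and -0.42 (limma adjusted p 2.8e-05) with the divisors removed.

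The comparison of both hairpins with control asked which of the listed genes fell with PD-L1 knockdown. The largest falls belonged to SLC7A11, the cystine transporter that supplies glutathione synthesis, and to the inflammatory cytokine IL6. SLC7A11 fell to 4.14% of control with hairpin 1 and 3.92% with hairpin 2 as deposited, and to 9.12% and 10.2% with the divisors removed. IL6 fell to 5.80% and 3.23% as deposited, and to 12.8% and 8.39% with the divisors removed. Other inflammatory genes among the 20 largest falls were the chemokine CXCL2, the cytokines IL24, IL1A and CSF2, and DUSP1, a phosphatase that switches off stress kinases. Genes of amino acid supply and stress were also among them: PSAT1 of serine synthesis, the mitochondrial carboxykinase PCK2 and the pseudokinase TRIB3. The rest of these 20 were the keratin KRT81, the muscle-type adaptor FHL1, the AP-1 partner JDP2, the membrane protein MCTP1, the linker histones H1F0 and H1FX, the kinase PRKCE, the matrix protein ADAMTSL4, the cholesterol carrier STARD4 and the nuclear pore protein NUP210.

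Values for these 20 genes ran, in log2 change for both hairpins, from -4.63 for SLC7A11 and -4.53 for IL6 to -3.16 for CSF2 and -3.15 for PCK2 on the deposited scale. The same genes ran, with the divisors removed, from -3.37 and -3.27 to -1.90 and -1.89, with every knockdown library below both control libraries on the deposited scale. SLC7A11 had deposited means of 13563 ± 40.3 (SD, n = 2) in control, 562 ± 12.5 (SD, n = 2) with hairpin 1 and 531 ± 7.35 (SD, n = 2) with hairpin 2. IL6 had means of 44632 ± 34.7 (SD, n = 2), 2589 ± 28.9 (SD, n = 2) and 1440 ± 48.7 (SD, n = 2).

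**Figure D2:**
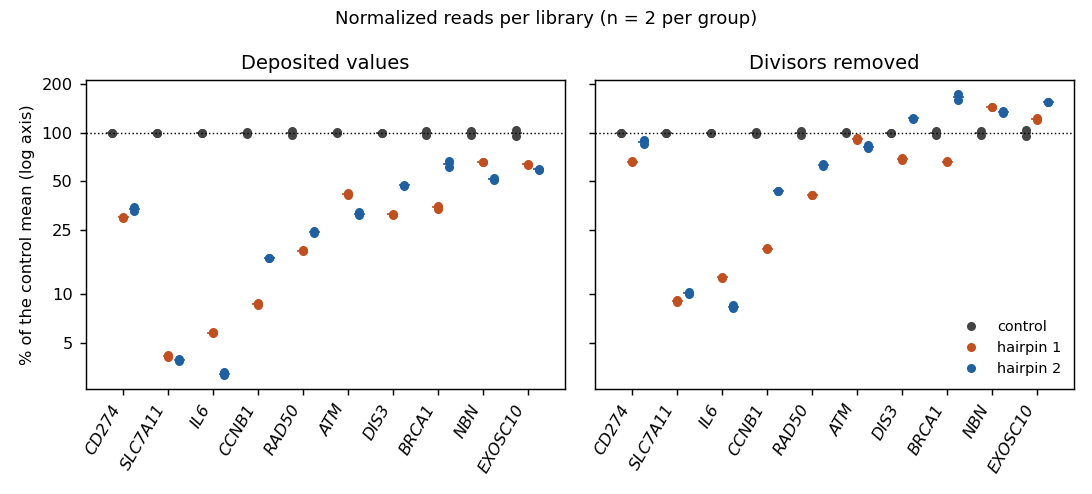
Percent of the control mean (y axis, log scale) for CD274 and 9 other named genes in each library, on the deposited scale and with the divisors removed. Points are libraries and short lines their means, and CD274 lies at 30.1% and 33.9% of control as deposited against 66.1% and 88.2% with the divisors removed.

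Over the list, limma called 6502 genes lower and 0 higher for both hairpins against control on the deposited scale, at an adjusted p under 0.05, and no gene was higher at an unadjusted p under 0.05 either. With the divisors removed, limma called 2771 genes (42.6%) lower and 2617 (40.2%) higher, and 1114 were not called. Taking the 4 knockdown libraries as 1 group, so that differences between the hairpins count as spread, it called 1260 lower and 903 higher. Against the criteria of the design text, 6498 genes were lower and 0 higher as deposited, and 811 were lower and 62 higher with the divisors removed. These counts describe genes selected for being lower on the deposited scale. With the divisors removed, the largest ratio to control of any listed gene was 1.496 with hairpin 1 and 1.76 with hairpin 2. Larger rises are thus cut off by the list, and the 62 genes cannot be weighed against the 811.

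Of the fixed lists tested, cytokine genes controlled by NF-kB, a transcription factor of inflammation, lay furthest below the other listed genes. All 8 listed members, of 22 in the list, fell on the deposited scale, and 7 fell while 1 rose with the divisors removed. Relative to the median of all listed genes, their median was -1.51, and camera gave an adjusted p of 7.7e-07 as deposited and 0.017 with the divisors removed (0.38 and 0.56 with estimated correlation). Of 15 listed genes of the unfolded protein response, which relieves the endoplasmic reticulum of misfolded protein, 10 fell and 2 rose with the divisors removed, where all fell as deposited. Their relative median was -0.53, with camera adjusted p 0.0055 as deposited and 0.024 with the divisors removed (0.59 and 0.69 with estimated correlation). The falls, given as log2 changes as deposited and with the divisors removed, were led by TRIB3, the chaperone HSPA5 (-2.67 deposited, -1.41 removed), and the transcription factors ATF4 (-2.52 deposited, -1.27 removed) and XBP1 (-2.46 deposited, -1.20 removed). Of 18 listed genes of cholesterol synthesis, 13 fell and 4 rose with the divisors removed, where all fell as deposited, with a relative median of -0.50 and camera adjusted p of 0.017 and 0.026 (0.38 and 0.56 with estimated correlation). As deposited, that call was lost without control replicate 2 (camera adjusted p 0.054). STARD4, the squalene synthase FDFT1 (-2.69 deposited, -1.43 removed) and the regulator SREBF2 (-2.33 deposited, -1.07 removed) were among those that fell. The 5 listed mitosis genes, of 27 in the list, had a relative median of -0.94 and camera adjusted p of 0.0055 as deposited and 0.11 with the divisors removed (0.38 and 0.65 with estimated correlation), where 4 fell and 1 rose. Mitosis was led by cyclin B1, CCNB1 (-3.04 deposited, -1.79 removed), and by CENPF, TTK and MAD2L1, all lower on both scales.

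Genes of oxidative phosphorylation and ribosomal proteins were lower as deposited and mostly higher with the divisors removed. All 24 listed oxidative phosphorylation genes fell as deposited, and 18 rose and 0 fell with the divisors removed, with camera adjusted p 0.57 as deposited and 0.0036 upward with the divisors removed (0.80 and 0.56 with estimated correlation). All 30 ribosomal protein genes fell as deposited, and 19 rose and 2 fell with the divisors removed, with camera adjusted p 0.65 and 0.024 (0.92 and 0.69 with estimated correlation). For ribosomal proteins the deposited test pointed down while the relative median was 0.12. With the divisors removed, listed genes of higher expression level tended to be higher (Spearman rho 0.22, both hairpins). That trend was not removed for these 2 lists. With the correlation estimated from the data, 0 of the 23 lists passed the camera threshold on either scale, and the smallest adjusted p was 0.38 as deposited and 0.56 with the divisors removed. Counted with p-values adjusted over the list alone, the numbers of lower and higher genes for both hairpins against control were the same as over all genes in every fixed list except nucleotide excision repair.

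In the comparison of both hairpins with control, the other lists were not past the camera threshold on either scale, and all their listed members fell as deposited. With the divisors removed, interferon response, led by the antiviral MX1 (-3.01 deposited, -1.76 removed), had 8 lower and 2 higher genes of 13. Among repair lists, homologous recombination had 3 lower and 6 higher of 12, end joining 5 and 5 of 12, mismatch repair 3 and 3 of 8, base excision repair 5 and 3 of 8, Fanconi anemia genes 4 and 3 of 8, and the damage checkpoint 8 and 6 of 14. Nucleotide excision repair had 7 lower and 8 higher of 20, and 7 and 7 adjusted over the list alone. DNA replication had 2 lower and 6 higher of 8 and p53 targets 7 and 4 of 13. The RNA exosome, which degrades RNA from its 3-prime end, had 7 lower and 6 higher of 17. Large chromatin genes had 11 lower and 8 higher of 23, KRAB zinc finger genes 1 and 4 of 8, glycolysis and hypoxia 4 and 7 of 11, and the mesenchymal program 4 and 2 of 7. Antigen presentation had 3 lower and 3 higher of 7, with the immunoproteasome gene PSMB9 (-2.15 deposited, -0.89 removed) falling most, and immune checkpoint ligands had 2 and 3 of 7. Epithelial genes had 3 listed members, of which 0 were lower and 1 was higher, and were too few to test. Replication histones, mitochondrial transcripts, fibroblast genes and blood cell genes had 0 listed members.

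**Figure D3:**
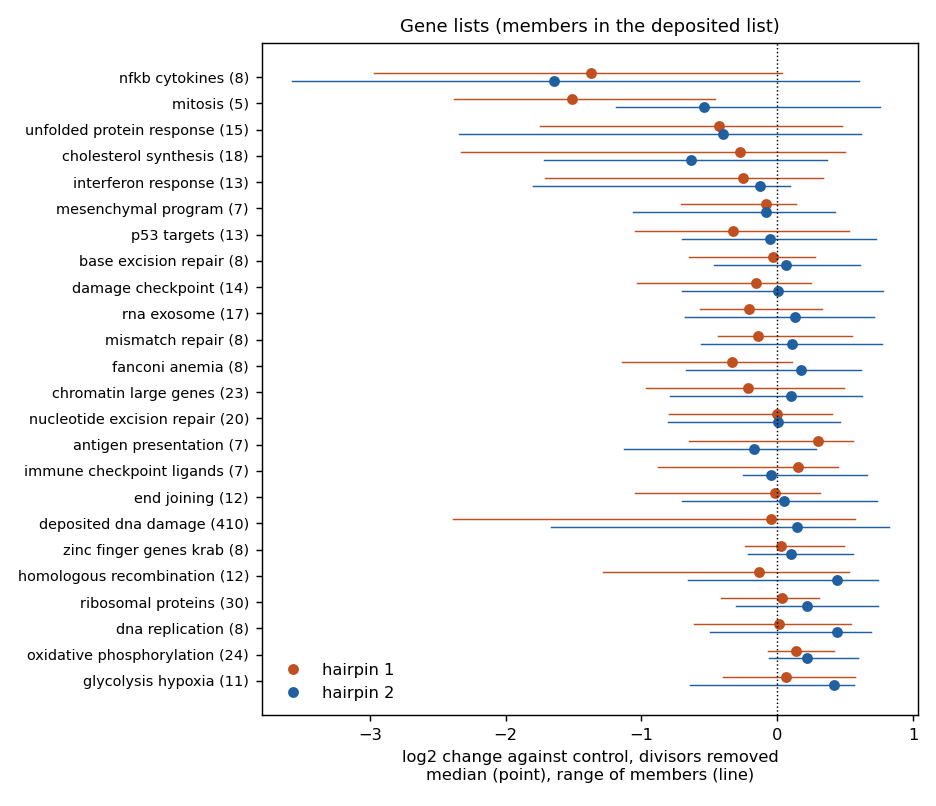
Log2 change against control with the divisors removed (x axis) for each gene list (y axis, listed members in brackets), with the median as a point and the range of members as a line. NF-kB cytokine, unfolded protein response and cholesterol medians lie below 0 with both hairpins, while on the deposited scale every member of every list was lower.

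The authors' DNA damage list was chosen by the study on these samples and is not independent evidence of direction. All 410 genes were lower as deposited, and with the divisors removed limma called 160 lower and 197 higher, with 53 not called. Adjusted over the list alone, 198 were higher, which is not independent evidence either. Their median log2 change with the divisors removed was 0.063 while the mean was -0.032, and camera did not separate them from the other listed genes (p 0.61 as deposited and 0.25 with the divisors removed, and 0.63 and 0.32 with estimated correlation). The largest falls in the list were CDKN3, a phosphatase of cell cycle kinases (-3.12 deposited, -1.86 removed), CCNB1, the p53 cofactor JMY (-2.91 deposited, -1.66 removed), the death adaptor CRADD and the fork remodeller HLTF. APBB1, HMGN1, USP28, CSNK1E and RAD50 completed the 10 largest, and all 10 stayed lower with the divisors removed, from -1.86 to -0.97. With hairpin 1 alone 187 genes of the list were lower and 140 higher with the divisors removed, and with hairpin 2 alone 130 and 221, while all 410 were lower with each as deposited. Relative to the other listed genes, camera passed the list upward with hairpin 2 and the divisors removed (p 0.037, and 0.12 with estimated correlation), but not as deposited (0.15) or with hairpin 1 (0.59 and 0.95). Between the hairpins, 153 were lower and 184 higher with hairpin 1 as deposited, but 250 lower and 90 higher with the divisors removed (91 higher adjusted over the list alone). Against the other listed genes, which as a whole were more often higher with hairpin 1 as deposited and more often lower with the divisors removed, camera placed the list lower with hairpin 1 on both scales (p 0.0075 and 0.0099, and 0.069 and 0.078 with estimated correlation).

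The genes fixed in advance act in double-strand break signalling or RNA degradation. RAD50, the ATPase of the MRN complex that senses breaks, fell on both scales, to 18.7% of control with hairpin 1 and 24.4% with hairpin 2 as deposited and to 41.1% and 63.5% with the divisors removed. NBN, its signalling subunit, fell to 65.6% and 51.9% as deposited but stood at 144% and 135% of control with the divisors removed. The kinase ATM fell on both scales, with a log2 change of -1.46 as deposited and -0.20 with the divisors removed. BRCA1, of homologous recombination, fell to 34.6% and 64.3% as deposited and stood at 66.3% with hairpin 1 and 167% with hairpin 2 with the divisors removed. The exosome nuclease EXOSC10 fell to 63.9% and 59.4% as deposited and stood at 122% and 154% with the divisors removed. The nuclease DIS3 fell to 31.3% and 47.2% as deposited and stood at 68.8% and 123% with the divisors removed. The hairpin 1 values of BRCA1 and EXOSC10 carry the second, smaller divisor.

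Each hairpin against control asked what each knockdown changed by itself. For hairpin 1, limma called 6502 listed genes lower and 0 higher as deposited, with 0 higher at an unadjusted p under 0.05, and 2983 lower and 2274 higher with the divisors removed. For hairpin 2 it called 6502 lower and 0 higher as deposited, again with 0 higher at an unadjusted p under 0.05, and 2637 lower and 2885 higher with the divisors removed. Relative to other listed genes, NF-kB cytokines were lower with each hairpin, with camera adjusted p of 1.2e-05 and 7.0e-06 as deposited (0.27 and 0.34 with estimated correlation) and 0.027 and 0.0071 with the divisors removed (0.69 and 0.46 with estimated correlation). Mitosis genes were lower with hairpin 1 (camera adjusted p 0.00013 as deposited and 0.020 with the divisors removed, and 0.27 and 0.69 with estimated correlation). With hairpin 2 alone they did not pass (camera adjusted p 0.25 as deposited and 0.23 with the divisors removed). Cholesterol synthesis genes were lower with hairpin 2 (camera adjusted p 0.0032 and 0.00079, and 0.34 and 0.46 with estimated correlation). With hairpin 1 alone the cholesterol list did not pass (camera adjusted p 0.32 as deposited and 0.35 with the divisors removed). Unfolded protein response genes passed camera with hairpin 2 (adjusted p 0.0032 and 0.0096, and 0.49 and 0.46 with estimated correlation), and with hairpin 1 only as deposited (0.047, or 0.80 with estimated correlation, and 0.23 with the divisors removed). Homologous recombination genes passed camera upward with hairpin 2 as deposited (adjusted p 0.0042, or 0.40 with estimated correlation). They did not pass with the divisors removed (0.20), although the single hairpin 2 divisor leaves their distance from the other listed genes nearly unchanged. The deposited call alone thus does not show a smaller fall. Oxidative phosphorylation genes passed upward with the divisors removed, with hairpin 1 (camera adjusted p 0.0080) and hairpin 2 (0.0096), as did ribosomal proteins with hairpin 2 (0.0055). These upward calls did not hold with estimated correlation either (0.69 with hairpin 1 and 0.46 with hairpin 2).

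The hairpins were compared for overlap because a hairpin can also act on unintended transcripts. With the divisors removed, 1903 listed genes were lower with both hairpins, where 1210 were expected if the calls were independent, and 1577 were higher with both, where 1009 were expected. Simulated unchanged groups sharing the control libraries gave 0 shared calls. These simulations held no hairpin effects, so they cannot show how far separate effects would overlap. Neither they nor the independent expectation model the selection of the listed genes. A further 690 genes were lower with hairpin 1 and higher with hairpin 2, and 361 the reverse. Across genes the log2 changes had a Pearson r of 0.66 and a Spearman rho of 0.58 with the divisors removed, against a simulated r of 0.50, and the covariance was 0.156 against 0.0012. On the deposited scale all 6502 genes were lower with both. The bound on the hairpin ratio of listed genes sets part of this overlap. With a control library of its own for each hairpin and the divisors removed, 1779 or 1756 genes were lower with both, depending on which control went with which hairpin, and 1441 or 1431 higher with both, with a Pearson r across genes of 0.66 in either case.

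**Figure D4:**
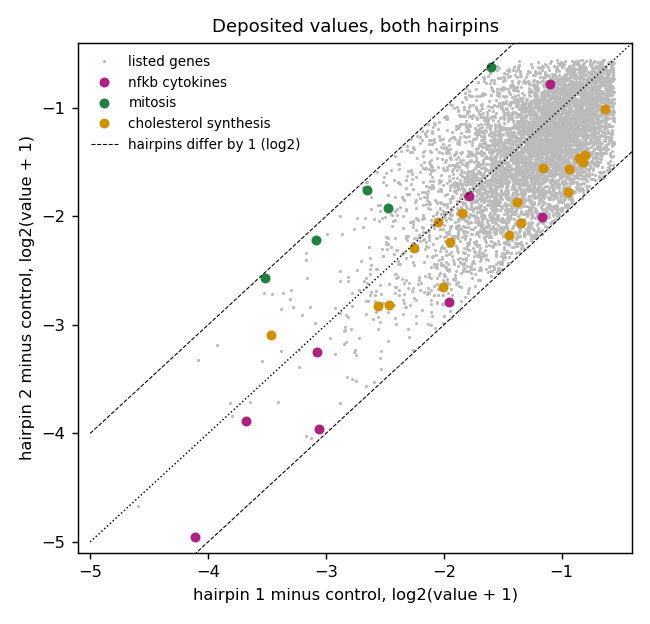
Log2 change against control with hairpin 1 (x axis) and hairpin 2 (y axis) on the deposited scale, each grey point a listed gene, with NF-kB cytokine, mitosis and cholesterol synthesis genes in colour. The points end along the dashed lines where the hairpins differ by 1 log2 unit, and the 5 mitosis genes lie on the side lower with hairpin 1, at differences from -0.97 to -0.55.

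The direct comparison of the hairpins asked which genes they changed unequally. Mitosis genes were lower with hairpin 1: all 5 listed members fell relative to hairpin 2, with a relative median of -1.05 on both scales and camera adjusted p 0.00081 as deposited and 0.023 with the divisors removed (0.39 and 0.49 with estimated correlation). CCNB1 fell to 8.73% of control with hairpin 1 and 16.9% with hairpin 2 as deposited, and to 19.2% and 43.8% with the divisors removed. Limma called 1708 genes lower and 3623 higher with hairpin 1 than with hairpin 2 as deposited, and 3169 lower and 2076 higher with the divisors removed. Among lists that differed at the preset correlation, homologous recombination (camera adjusted p 0.013) and Fanconi anemia genes (0.019) were lower with hairpin 1 as deposited and missed the threshold with the divisors removed (0.062 for both). With the divisors removed, ribosomal proteins were lower, and antigen presentation and cholesterol synthesis genes higher, with hairpin 1 (camera adjusted p 0.023 each), and none of these held with estimated correlation (0.39 or above). UBE2T, a ubiquitin enzyme of crosslink repair, and PAICS, of purine synthesis, were among the genes lowest with hairpin 1 relative to hairpin 2, both at -0.99 as deposited and -1.23 with the divisors removed. CITED2, a transcription cofactor, was higher with hairpin 1, at 1.00 and 0.75. The largest differences lay near the bound of the list, so genes with larger ones would not have been listed.

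In the authors' deposited table of enriched terms, 124 entries covered 123 distinct gene ontology terms, 104 over-represented and 19 under-represented among the submitted genes. The authors' deposited table gave the smallest p-value to cellular metabolic process, with 3827 of 8846 genes, a fold of 1.39 and p 1.4e-155. Next in the authors' deposited table were organelle organization (fold 1.62, p 2.6e-80), cellular component organization (fold 1.4, p 4.3e-69), gene expression (fold 1.5, p 4.1e-67), cellular biosynthetic process (fold 1.4, p 4.1e-58) and organic substance biosynthetic process (fold 1.39, p 4.5e-58). The authors' deposited table also held 2 under-represented terms among its 10 smallest p-values, G-protein coupled receptor signaling pathway (fold 0.29, p 2.8e-57) and detection of chemical stimulus involved in sensory perception (2 of 467 genes, p 2.0e-56). Protein localization (fold 1.68, p 1.4e-53) and intracellular transport (fold 1.82, p 6.7e-51) completed the 10 in the authors' deposited table. For DNA damage, the authors' deposited table listed cellular response to DNA damage stimulus with 409 of 729 genes, a fold of 1.81 and p 4.3e-25. DNA repair had 276 of 489 genes, a fold of 1.82 and p 2.5e-16, and DNA damage checkpoint 87 of 143 genes, a fold of 1.96 and p 7.6e-05, in the authors' deposited table. The background set behind the authors' deposited table is not given in the sources used here. Its term totals include genes of sensory perception of smell, a term that was under-represented. No comparison with expressed genes that were not lowered is given. The folds, those of the DNA damage terms included, thus cannot separate lowering by knockdown from expression in these cells.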

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

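In this part, the tests of a constant divisor, read numbers, spike-ins, single-hairpin effects and CD274 level, and every test with the divisors removed, were chosen after the results were seen.

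The hairpins differed from each other in many listed genes, tested directly with limma. As deposited, 1708 genes were lower and 3623 higher with hairpin 1, and with the divisors removed 3169 were lower and 2076 higher. The genes with the largest log2 difference were lower with hairpin 1 for BAHD1 (-0.997), UBE2T (-0.99), CHCHD1 (-0.99), PRKAR2A (-0.99) and PAICS (-0.99). They were higher with hairpin 1 for RABAC1 (1.00), MTMR11 (1.00), VAMP4 (1.00), CITED2 (1.00) and CCDC115 (1.00). All 10 keep these directions with the divisors removed, and all lie near the 2-fold bound of the list. Of the genes fixed in advance, BRCA1 and DIS3 moved in opposite directions with the hairpins once the divisors were removed. Their log2 differences were then -1.33 and -0.84, while both fell with both hairpins as deposited.

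Some gene lists differed between the hairpins relative to the other listed genes, by camera at the preset correlation. As deposited, the relative medians were -0.39 for Fanconi anemia genes, -0.48 for homologous recombination and -1.05 for mitosis. On the other scale, with the divisors removed, they were 0.56 for antigen presentation, 0.29 for cholesterol synthesis, -1.05 for mitosis and -0.13 for ribosomal proteins. None of these lists passed with estimated correlation, where the smallest adjusted p was 0.39 as deposited and 0.49 with the divisors removed. Without hairpin 2 replicate 1, Fanconi anemia and homologous recombination genes also passed with the divisors removed, at camera adjusted p 0.037 and 0.041, and without hairpin 2 replicate 2 homologous recombination did at 0.037. As deposited, cholesterol synthesis genes passed without hairpin 2 replicate 2 (0.049) and not with all libraries (0.057).

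Every listed gene was lower in the knockdown columns. The divisors set this level, since the median log2 change was -0.0043 once they were removed. Then 45.0% of listed genes with hairpin 1 and 52.4% with hairpin 2 stood above control. Fewer reads in the listed genes are argued against, because the mean number of rebuilt reads was 1.15 times that of control. Whether the divisors correct for a lower amount of RNA per cell cannot be told, because 0 libraries have a spike-in or cell count in their labels. The list itself was selected for being lower on the deposited scale, so it gives no view of genes outside it.

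NF-kB cytokine, unfolded protein response and cholesterol synthesis genes were lower than the other listed genes at the preset correlation, and all 3 camera calls were lost with estimated correlation (adjusted p 0.38 to 0.59 as deposited and 0.56 to 0.69 with the divisors removed). The divisors shift nearly all listed genes alike, so no test of them was made here, and no biological explanation was tested. GC content and transcript length are argued against, as the highest of the 3 relative medians was -0.51 after these trends were removed (-0.55 to -0.47 with single libraries left out). The trends were weak to begin with (Spearman rho 0.063 with GC content and -0.093 with length, both hairpins, divisors removed). A larger trend with expression level (rho 0.22) was not removed. With the divisors removed, the higher relative median of the hairpins was -1.32 for cytokine genes. For unfolded protein response genes it was -0.37 with hairpin 1 (-0.42 to -0.35), against -0.43 with hairpin 2. The unfolded protein response list passed camera with hairpin 1 as deposited (adjusted p 0.047, lost without either control library and at 0.80 with estimated correlation). With the divisors removed it did not pass (0.23). Cholesterol genes stood at -0.22 with hairpin 1 (-0.25 to -0.20) and -0.66 with hairpin 2. An effect of 1 hairpin only stays open for all 3 lists, because listed genes were selected to be lower with both hairpins and within the 2-fold hairpin bound. Members that fell far with 1 hairpin and stayed level with the other would be missing.

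Mitosis genes were lower with hairpin 1 than with hairpin 2. Their camera call was lost with estimated correlation (adjusted p 0.39 as deposited and 0.49 with the divisors removed), and the divisors shift nearly all listed genes alike, so no test of them was made here. GC content with transcript length is argued against by a relative median of -1.02 after correction (-1.05 to -0.99). A lower PD-L1 transcript level with hairpin 1 is a possible explanation, since CD274 differed in the same direction by -0.17 as deposited and -0.42 with the divisors removed, against -1.05 for the mitosis median on both scales, but with 2 hairpins an effect of either sequence on other transcripts stays open and untested. Only 5 of 27 mitosis genes are listed, at differences from -0.97 to -0.55 as deposited, and members beyond the hairpin bound would be missing.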

How the results depend on the processing

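The settings with the divisors removed, with 1 divisor per hairpin, with precision weights and with a control library of its own for each hairpin were chosen after seeing the data; the other settings were planned.

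On the deposited scale, genes kept their direction and side of the threshold, and counts stayed within 1.5 times, for the results run under each of the next settings. These settings were pseudocounts of 0.1 and 5, 1 divisor per hairpin, an adjusted p threshold of 0.01, only the compared groups in the fit, and the mean over 100 taken in control libraries alone. Precision weights, with the divisors removed, kept direction and side of the threshold for each named gene run and moved the counts slightly, to 2819 genes lower and 2637 higher for both hairpins (2771 and 2617 without weights). A control library of its own for each hairpin kept the overlap counts within 1.5 times, at 1756 to 1779 lower and 1431 to 1441 higher with the divisors removed. Planned tests with edgeR and DESeq2 and trimmed mean scaling were not run, as the deposited values are not whole counts, and the low-value filter would have removed no gene.

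Removing the divisors, or scaling the rebuilt reads by median-of-ratios or by totals over the listed genes, changed the counts, because the divisors set the level of the knockdown columns. In that order, genes lower for both hairpins against control were 2771, 2717 and 2688, and genes higher 2617, 2691 and 2727, against 6502 and 0 as deposited. With hairpin 1, 2983, 2695 and 2626 were lower and 2274, 2641 and 2765 higher, and with hairpin 2, 2637, 2781 and 2811 were lower and 2885, 2703 and 2670 higher. Hairpin 1 was lower than hairpin 2 in 3169, 2585 and 2449 genes and higher in 2076, 2653 and 2804. The criteria of the design text gave 811, 793 and 779 genes lower and 62, 76 and 92 higher. Genes lower with both hairpins were 1903, 1840 and 1815, and higher with both 1577, 1688 and 1735. The DNA damage list had 160, 158 and 155 genes lower and 197, 204 and 204 higher. CD274 stayed lower, with log2 changes of -0.39, -0.38 and -0.37.

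Log2 changes of 17 named genes reversed from a fall to a rise under all of these scalings, in the same order, and the removed divisors show the cause. They were NLRC5 (0.0066, 0.017 and 0.022), ORC3 (0.082, 0.092 and 0.10), RRM1 (0.18, 0.19 and 0.20), CLDN4 (0.0013, 0.011 and 0.017), GATA3 (0.10, 0.11 and 0.12) and KRT18 (0.24, 0.25 and 0.25). Further ones were MUS81 (0.053, 0.063 and 0.068), CD47 (0.041, 0.051 and 0.056), UQCRC1 (0.0055, 0.016 and 0.021), COX7C (0.038, 0.048 and 0.053), NDUFV1 (0.058, 0.068 and 0.074) and ZNF28 (0.049, 0.059 and 0.065). The last were PAICS (0.12, 0.13 and 0.14), MTMR11 (0.11, 0.12 and 0.13), NBN (0.48, 0.49 and 0.50), BRCA1 (0.074, 0.084 and 0.089) and EXOSC10 (0.46, 0.47 and 0.48). PVRL2 reversed under median-of-ratios (0.0056) and totals (0.011) alone. Of these, RRM1, KRT18, ORC3, PAICS, MTMR11, NBN and EXOSC10 passed the limma threshold as higher with the divisors removed. Another 9 named genes stayed lower but lost the call with the divisors removed.

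Taking the 4 knockdown libraries as 1 group, with the divisors removed, gave 1260 genes lower and 903 higher, because differences between the hairpins then count as spread. With estimated correlation, 0 fixed lists passed the camera threshold, as deposited or with the divisors removed, against 4 and 5 at the preset correlation.

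Leaving out each library in turn, with the lone library of its group assumed to vary like the other groups, gave 2606 to 2755 genes lower and 2397 to 2587 higher for both hairpins with the divisors removed. Of 201 gene, count and total-list results, 200 were kept whichever library was absent. Kept means the same call and direction for a tested result, and within 1.5 times for a count. Directions against control on the deposited scale were fixed by the selection of the list. BRCA1 with the divisors removed was the exception, higher by a log2 change of 0.10 (limma adjusted p 0.042) without hairpin 2 replicate 1, against 0.074 (limma adjusted p 0.15) with all libraries. On the deposited scale 3 to 4 fixed lists passed, as cholesterol synthesis lost its call without control replicate 2 (camera adjusted p 0.054). Unfolded protein response genes with hairpin 1 as deposited lost theirs without either control library.

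A replicate block, with the replicate number as a term, kept direction and side of the threshold for each named gene and moved the counts slightly, to 2778 genes lower and 2614 higher for both hairpins with the divisors removed. Deviations of same-numbered libraries from their group means correlated across genes at r of 0.048, 0.030 and 0.0048, so the numbers do not pair the libraries.

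Read numbers limit little here, as every listed gene had at least 291 rebuilt reads in each library.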

Other observations

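The second-divisor test and every added gene group except ATF4 targets were chosen after the results were seen; the ATF4 test was set after 4 falling genes were seen but before its own result.

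SLC7A11, PSAT1, PCK2 and TRIB3, all among the 20 largest falls, are known targets of ATF4, the transcription factor of the amino acid and endoplasmic reticulum stress response. A list of other ATF4 targets, without these 4 and without targets already seen in the fixed lists, had 19 listed members, of which 17 fell and 2 rose with the divisors removed and all fell as deposited. Its median relative to all listed genes was -0.93 with the divisors removed, with camera adjusted p 1.5e-05 (0.15 with estimated correlation), and -0.86 and -0.85 with hairpin 1 and hairpin 2. Members with large falls, named after their values were seen, were the alanyl-tRNA synthetase AARS (-1.74), CEBPB (-1.30), CEBPG (-1.27), SHMT2 (-1.23) and MTHFD2 (-1.05), with the divisors removed. ATF4 itself fell by 1.27 on that scale, while its activity was not measured. Of the 19 members, 9 are tRNA synthetases, and the other 10 had 8 lower and 2 higher, with a relative median of -0.96 (camera p 0.0040, and 0.099 with estimated correlation).

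Other groups moved apart from the median of all listed genes, while every member was lower as deposited. Among listed proteasome genes, 27 of 30 were higher and 1 lower with the divisors removed (camera adjusted p 2.2e-06), as were 17 of 20 mitochondrial ribosome genes with 1 lower (0.00034), 13 of 17 spliceosome genes with 3 lower (0.0073), and 13 of 20 genes of protein entry to the endoplasmic reticulum with 3 lower (0.029). All 4 calls were lost with estimated correlation (camera adjusted p 0.15 each). Listed genes of higher expression level tended to be higher on this scale (Spearman rho 0.22, both hairpins), and that trend was not removed for these groups. Cytosolic tRNA synthetases had 9 lower and 3 higher of 13 (0.029, or 0.16 with estimated correlation), and the 9 lower ones are the 9 that the ATF4 list also holds, so this is not a separate result. Of the 4 outside the ATF4 list, limma called 3 higher and did not call 1. Immediate early genes had 9 lower and 2 higher of 14 (0.029, or 0.33 with estimated correlation). With single hairpins and the divisors removed, camera did not pass for spliceosome genes, tRNA synthetases and immediate early genes with hairpin 1 (adjusted p 0.053, 0.19 and 0.091), nor for protein entry to the endoplasmic reticulum with hairpin 2 (0.086). On the deposited scale, camera did not pass for proteasome (adjusted p 0.19), mitochondrial ribosome (0.061), spliceosome (0.74) or protein entry to the endoplasmic reticulum genes (0.74). With single hairpins and estimated correlation no group passed camera with the divisors removed, the smallest adjusted p being 0.19 with hairpin 1 and 0.13 with hairpin 2. The linker histones H1F0 and H1FX were the only 2 listed of 7 and were not tested.

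For 90 genes the hairpin 1 values carry a smaller divisor than the rest. With the common divisor, 8 of them, or 8.89%, would have left a bound of the list, 6 by the smallest value and 2 by the hairpin ratio, so the bounds are argued against as the whole cause. The authors' DNA damage list held 7 of the 90, where 5.68 were expected (Fisher exact p 0.51, two-sided). The reason for the smaller divisor is not given in the sources used here.

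In the authors' deposited table, folds of over-represented terms followed 1 expected share of each term's genes, within 10% for all but 1 term, cellular protein modification process, with 664 of 3003 genes and a fold of 1.48.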
